A study of Homo sapiens with 6 samples.

How the data were processed

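RNA was sequenced from CD34+ cells of umbilical cord blood that were grown for 6 days in an erythroid culture medium, sorted for the transferrin receptor CD71, and then kept for 24 h with 10 µM enasidenib (AG221) or with its solvent DMSO, per the labels' protocols. Enasidenib is a small-molecule inhibitor made against mutant forms of the mitochondrial enzyme IDH2. Libraries were made from 500 ng of total RNA with an Illumina TruSeq version 2 kit, per the labels' protocols. The labels name the medium supplement for erythroid expansion in one place and for erythroid differentiation in another.

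The deposited table holds whole read counts per gene for 6 libraries, 3 per treatment, with no normalization. It has 17783 genes, each with 1 RefSeq transcript and its position, and every gene in it has at least 6 counts over all libraries together. The submitters' processing notes name the genome build hg38 and the tool DESeq2, without saying how the authors used the latter. The aligner, the counting tool, the use of strand and whether single reads or read pairs were counted are not given in the sources used here. Counts from 1 to 19 were even in 53.2% to 57.7% of cases per library. Start positions in the table count from 0 (29.1% of 15900 genes matched by symbol and chromosome begin exactly 1 base below the RefSeq start, and 3.11% begin at it), so starts are given here with 1 added. No mitochondrially encoded gene was analysed here, so the planned share and list of those genes were not computed. Genes with near-identical copies, such as HBA1 and HBA2, HBG1 and HBG2, HBB and HBD in part, and IL9R with its pseudogenes, have uncertain counts. The same holds for overlapping and antisense genes, since the use of strand is unknown.

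Total counts per library were 37141122, 79667059 and 40176313 for DMSO replicates 1, 2 and 3, and 54610969, 40539876 and 23343706 for enasidenib replicates 1, 2 and 3. Y-linked genes and X-inactivation transcripts, 24 in all, were taken out before library sizes were computed, which left 17759 genes. After edgeR's filter on low counts (filterByExpr), 14463 genes were tested. No pair of libraries within a group came within sampling noise of each other: the chi-square per degree of freedom between replicates ran from 95.8 to 421, so all 6 were counted as separate samples. The labels do not state that the replicates came from separate donors or cultures. The p-values of the model without a block therefore measure the spread between these samples, which may in part be technical. In the model with the replicate block, described below, they measure how the treatment difference varies over the 3 pairs. That model has 2 residual degrees of freedom per gene, and a median of 9.6 prior degrees is borrowed from all genes. Its gene p-values therefore rest mostly on the borrowed part.

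Counts were compared with edgeR 4.0.16 in R 4.3.3: TMM normalization, the quasi-likelihood test with treatment as the factor of the model, and Benjamini-Hochberg adjustment at 0.05. Gene values are CPM, which are counts scaled to TMM-adjusted library sizes, and log2 CPM used a prior count of 2. Replicate numbers come from the sample titles, in which replicate 1 carries no number and the others carry 2 and 3 after the letters cb, which may stand for cord blood units and are not explained in the labels. A model with the replicate number as a block was among the alternatives fixed before the data were examined. Whether the numbers pair the samples was tested by correlating, over genes, each library's deviation from its group mean. Same-numbered libraries had correlations of 0.52, 0.71 and 0.39, all above the limit of 0.1, and differently numbered ones had values of -0.52, 0.15, -0.51, -0.36, 0.16 and -0.47. The first principal component, with 54.1% of the variance, set both replicate 2 libraries apart. The numbers were therefore taken to pair the libraries, and blocked values are given wherever the block changed a call or moved a count by more than 1.5 times. Both models were run in the same first look as this correlation, and the rule for using the block had been fixed beforehand. The limit could not tell replicates 1 and 3 apart, since matching 1 with 3 also passed it (0.15 and 0.16). In log2 CPM, DMSO replicate 1 correlated most with enasidenib replicate 1 (0.970). DMSO replicate 3 correlated more with enasidenib replicate 1 (0.963) than with enasidenib replicate 3 (0.947). The pairing of replicates 1 and 3 is therefore less certain than that of replicate 2.

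The pre-set lists numbered 38, with 849 memberships, of which 823 were matched in the table by current or older symbols. The 37 lists with at least 5 tested genes entered camera with a preset correlation of 0.01 between genes, adjusted over all lists. The same test with an estimated correlation and the rotation test fry stood beside it. With an estimated correlation, camera takes its p from the residual degrees of freedom, 4 without the block and 2 with it. It therefore has little power here, and a call lost in it need not be due to correlated genes. Camera compares a list with all other genes. The main p of fry asks whether a list's own genes move, on balance, in one direction, and its mixed p whether they change in either direction. Shares of counts and the number of genes detected were compared by two-sided exact permutation tests over 3 against 3 libraries, in which the smallest possible p is 0.1.

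The rule for named genes was fixed before the data were examined. It takes IDH2 and IDH1 whatever their values, then up to 12 genes per direction with the largest change among those with an adjusted p under 0.05, a mean log2 CPM of at least 2 and one direction in all 3 pairs, and then the 4 members with the smallest p in each list. The middle part names no gene without the block. The 7 genes named from it come from the same rule applied to the blocked model, a step chosen after the values were seen, and only part of the list members that the rule allows are printed. ABCB1, ABCG2, AHR, CYP1A1, UGT1A6 and the lineage genes MPO, ELANE, LYZ, GATA1, KLF1, HBG1 and ALAS2 lie outside the rule and were chosen after their values were seen.

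Alternatives were DESeq2 1.42.0 and limma-voom (limma 3.58.1), DESeq2 size factors or the upper quartile in place of TMM, removal of globin genes, no filter or a filter of 50 counts in 3 libraries, thinning to the smallest library, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each library or each same-numbered pair. Blocked models in limma-voom, on thinned counts and without each pair, the blocked list test with an estimated correlation, and the aryl hydrocarbon receptor list without CYP1B1 were chosen after seeing the data. The models were tested on 5 simulated count sets of 14463 genes with 200 changed genes for the comparison of enasidenib with DMSO. With the block, 64.2% of 2-fold and 75.6% of 4-fold changes were recovered, with a mean of 158 calls, of which 8.8 were false and 9.4 were members of a list that had been shifted as well. Without the block, 0.8% and 32.2% were recovered, with 0 false calls, and a shifted list was called in 5 of 5 sets by both. The simulated counts carried the replicate differences and the spread of the blocked fit, so the gain from the block was built in. Genes were drawn independently of each other, so the list calls do not show how camera behaves with correlated genes.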

Results

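The comparison was of CD71+ erythroid progenitors from cord blood cultures after 24 h with 10 µM enasidenib (n = 3 libraries) against DMSO (n = 3), and it addresses which transcripts differ in cells treated with the drug. CD71, encoded by TFRC, is carried at high levels by dividing red cell precursors. Depth ran from 23343706 to 79667059 counts per library, and the deepest and the shallowest library belonged to different treatments. Values below are log2 fold changes of enasidenib against DMSO with standard errors (SE), from the model with the replicate number as a block (3 pairs) unless stated otherwise, with adjusted p from edgeR's quasi-likelihood test. Each SE was derived from the F value of that test, which borrows spread from other genes. It is not the spread of the gene's own 3 pair differences and can be smaller.

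CYP1B1 fell by 3.95 ± 0.21 on the log2 scale (SE from the test), a 15.5-fold lower level (adjusted p = 7.9e-06). Its differences in pairs 1, 2 and 3 were -3.25, -4.25 and -4.34. This gene encodes a cytochrome P450 whose transcription is induced through the aryl hydrocarbon receptor. AHRR, which encodes a repressor of that receptor and is itself one of its target genes, fell by 1.52 ± 0.19 (adjusted p = 0.0195). The other genes that fell were MMP2 (gelatinase A), IGFBP4 (a binding protein of insulin-like growth factors), ANPEP (aminopeptidase N, CD13), IL9R (the interleukin 9 receptor) and ITGAL (CD11a, the alpha chain of the integrin LFA-1). In all, 7 genes fell and 0 rose among 14463 tested. Each of the 7 was lower in 3 of 3 pairs, which the rule for named genes requires, so it adds no separate support. IDH2, which encodes the enzyme the drug was made against, had 217 ± 42.2 CPM with DMSO and 207 ± 49.2 CPM with enasidenib (SD, n = 3 each).

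These calls rest on the pairing of the libraries, which is less certain for replicates 1 and 3 than for replicate 2. Without the block, the model of treatment alone called 0 genes in either direction with edgeR, with 54 genes at an unadjusted p under 0.05 where chance alone gives 723. DESeq2 without the block called 1 gene, CYP1B1 (adjusted p = 3.3e-19), and limma-voom called 0. With the block, 825 genes had an unadjusted p under 0.05, DESeq2 called 27 genes (3 higher and 24 lower) and limma-voom 41 (10 higher and 31 lower), and both sets contained all 7. Over all tested genes, 2023 were higher and 2055 lower in all 3 pairs, together 28.2% against 25% by chance.

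CYP1B1 lies on chromosome 2 from 38067603 to 38076181 (hg38). Its level was 60.1, 129 and 183 CPM in DMSO replicates 1, 2 and 3 and 6.26, 6.77 and 9.01 CPM in the enasidenib replicates of the same numbers. The group means were 124 ± 61.6 and 7.35 ± 1.46 CPM (SD, n = 3 each), and without the block the log2 fold change was -4.08 ± 0.44 (adjusted p = 0.58). AHRR, on chromosome 5 from 304176 to 438290, went from 19.6, 90.5 and 45.3 CPM to 6.28, 45.6 and 11.7 CPM.

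MMP2 (chromosome 16, 55479169 to 55506691) fell by 1.71 ± 0.21 on the log2 scale (adjusted p = 0.016), from a mean of 67.9 ± 48.5 to 25.4 ± 25.8 CPM (SD, n = 3 each). IGFBP4 (chromosome 17, 40443424 to 40457730) fell by 1.09 ± 0.12 (adjusted p = 0.0075), from 177, 25.5 and 382 CPM to 92.2, 10.6 and 183 CPM. For ANPEP (chromosome 15, 89784895 to 89814840) the fall was 0.81 on the log2 scale, a 1.76-fold lower level (SE 0.11, adjusted p = 0.022), and its DMSO level ranged from 48.7 to 955 CPM, with the highest value in replicate 2. ITGAL (chromosome 16, 30472662 to 30523185) was 2.06-fold lower (log2 -1.04 ± 0.15) and IL9R (chromosome X, 155997581 to 156010817) 2.35-fold lower (log2 -1.23 ± 0.17), both with an adjusted p of 0.031. Without the block none of these 5 genes passed, with values such as -1.16 ± 0.58 for IL9R and -0.70 ± 1.43 for ANPEP. Leaving out pair 3 raised the adjusted p of ITGAL and IL9R to 0.067 each, and leaving out pair 2 raised that of ANPEP to 0.083.

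**Figure D1:**
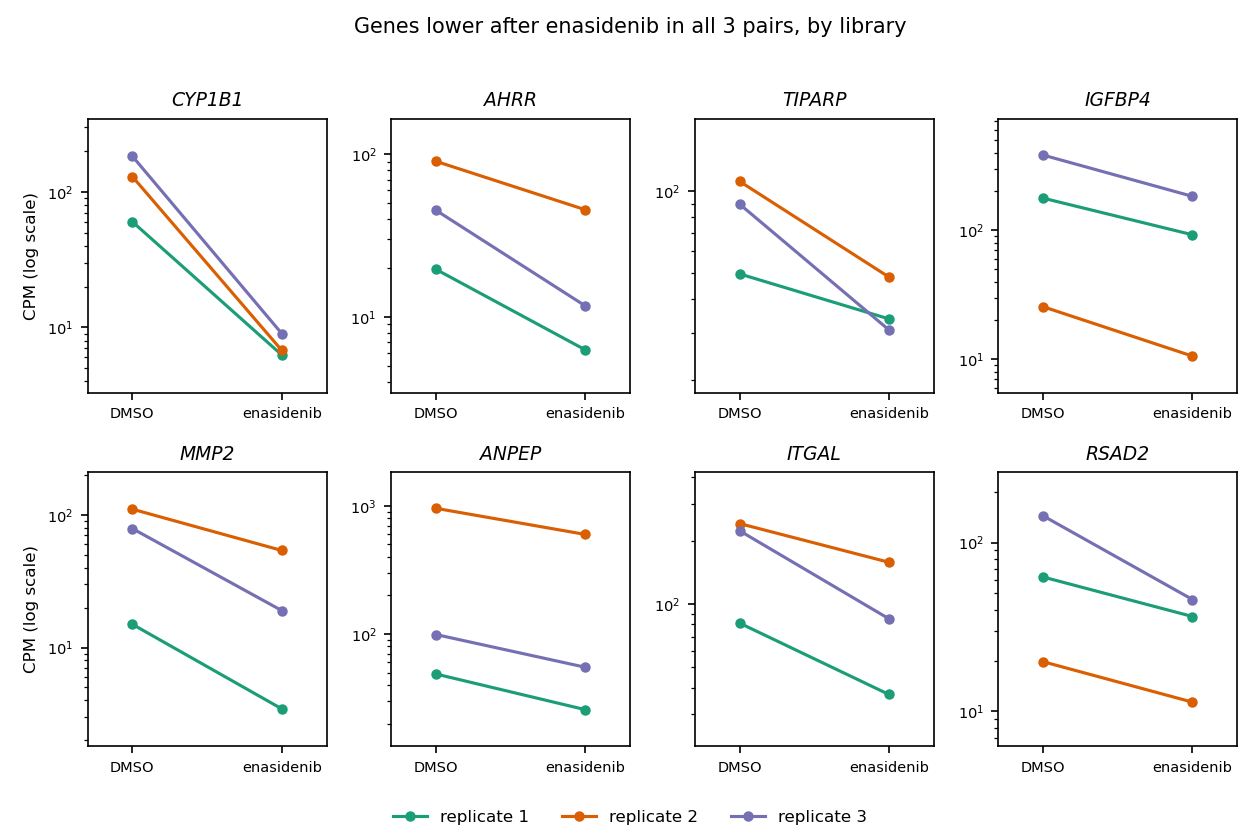
CPM (vertical, log axis) of 8 genes in the DMSO and enasidenib libraries, with a line joining libraries of the same replicate number. All lines slope down, and CYP1B1 reaches 6.26 to 9.01 CPM in the enasidenib libraries from 60.1 to 183 CPM in the DMSO libraries. TIPARP and RSAD2 did not pass the test over all genes.

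Of the 9 tested genes in the list of aryl hydrocarbon receptor and xenobiotic metabolism genes, 2 fell (CYP1B1 and AHRR), 0 rose and 7 did not pass over all genes, and 3 fell when adjusted over the list alone. The additional gene was TIPARP, an ADP-ribosyltransferase gene that the receptor induces, at -1.09 ± 0.18 (adjusted p = 0.074 over all genes, lower in 3 of 3 pairs). Its blocked adjusted p was 9.7e-05 without pair 1, 0.083 without pair 2 and 0.138 without pair 3, where it was at -0.86. The list was lower against all other genes by camera both without the block (adjusted p = 3.8e-07) and with it (adjusted p = 2.2e-14). Its median was only -0.05 without the block and -0.40 with it, so the call rests on a few members: 4 were lower in all 3 pairs (CYP1B1, AHRR, TIPARP and the sparsely counted UGT1A1) and 2 were higher in all 3 (AHR, and ABCB1 at 0.71 ± 0.40). With the correlation between genes estimated from the data it was not called (adjusted p = 0.993 with an estimated correlation without the block, and 0.857 with it). With the block that correlation was 0.088, and the unadjusted camera p was 0.023 against 5.9e-16 with the preset. The former test has only 2 degrees of freedom with the block, so the loss cannot be laid to correlated genes alone. Leaving out CYP1B1, the list had a camera p of 0.029 without the block and 4.0e-04 with it. Without the block, 2 genes of the list passed when adjusted over the list alone, and without replicate 3 in both groups the list's adjusted p was 0.097.

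The receptor's own gene, AHR, was at 0.18 ± 0.11. CYP1A1, a classical target gene of the receptor, passed the filter on low counts in too few libraries to be tested. It had counts of 0, 180 and 224 in DMSO replicates 1, 2 and 3, and of 6, 2 and 4 in the enasidenib replicates. With pair 1 left out it entered the test and was lower in the blocked model (adjusted p = 0.048), though it did not pass without the block. UGT1A6, a glucuronosyltransferase gene of the same list, had counts of 0, 37 and 4 with DMSO and 6, 9 and 2 with enasidenib.

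Genes of cholesterol synthesis and uptake were lower as a group. None of the 25 passed over all genes, 1 fell when adjusted over the list alone, and 10 were lower in all 3 pairs against 1 higher. HMGCS1, which makes HMG-CoA for the mevalonate pathway, was the 1 that passed over the list, at -0.56 ± 0.13, and at -0.37 without pair 3 (adjusted p = 0.943 over all genes). ACAT2 had -0.40 ± 0.12 and LSS, the lanosterol synthase, -0.37 ± 0.12. The list median was -0.18, and camera called the list lower without the block (adjusted p = 3.5e-04) and with it (adjusted p = 2.1e-06). Camera with an estimated correlation, which has little power here, did not call it (adjusted p = 0.993 without the block and 0.885 with it). Without the block the call was also lost without DMSO replicate 1 (adjusted p = 0.834), without enasidenib replicate 2 (0.224) and without replicate 3 in both groups (0.097).

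With the block, 4 more lists were called by camera in edgeR that the same TMM-scaled model did not call without it. None of these lists was called with an estimated correlation (adjusted p = 0.885 for each), a test with 2 degrees of freedom and little power. Their estimated correlations with the block ran from 0.14 to 0.46, above the preset 0.01. Markers of mast cells, basophils and eosinophils were higher (adjusted p = 9.8e-06, against 0.217 without the block), with a median of 0.44 over 14 genes. The mean was only 0.20, so the genes did not rise alike, and 3 of the 14 were higher and 0 lower in all pairs. Without the block the list passed under the stricter filter (0.036), without DMSO replicate 1 (0.044) and without replicate 1 in both groups (0.020). None of them passed over all genes, and 5 rose when adjusted over the list alone. They were CPA3, the mast cell carboxypeptidase, at 0.48 ± 0.11, MS4A2, a chain of the high-affinity IgE receptor, at 0.48 ± 0.14, ENPP3 at 0.44 ± 0.13, CLC at 0.50 ± 0.15 and RNASE2, an eosinophil ribonuclease, at 0.74 ± 0.23. CPA3, MS4A2 and ENPP3 were higher in 3 of 3 pairs, and CLC and RNASE2 in 2 of 3. The list took 0.316%, 0.243% and 0.233% of counts in DMSO replicates 1, 2 and 3 and 0.291%, 0.409% and 0.251% in the enasidenib replicates, so the difference in share was largest in replicate 2, whose libraries also stood apart by granulocyte transcripts. Without pair 2 the list's blocked adjusted p was 0.019, CLC was at 0.32 and RNASE2 at 0.43 with the block, and at 0.18 and 0.15 without it. Without pair 1 RNASE2 was at 1.19 with the block and CLC at 0.75, and both passed over all genes (adjusted p = 2.7e-04 and 0.016), as did CPA3 (0.039).

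Globin genes and AHSP were higher as a list (adjusted p = 5.6e-05, against 0.217 without the block), with a median of 0.34 over 10 genes (0.17 without the block). The pair medians were 0.01, 0.61 and 0.03 in replicates 1, 2 and 3, so the shift lay mainly in replicate 2, whose libraries also stood apart by granulocyte transcripts, and 2 of the 10 genes were higher in all pairs. Without the block the list passed in limma-voom (adjusted p = 0.035) and, in edgeR, without DMSO replicate 1 (1.7e-08), enasidenib replicate 2 (0.013), enasidenib replicate 3 (0.020) or replicate 1 in both groups (0.0073). None passed over all genes and 1 rose when adjusted over the list alone: HBD, which encodes delta-globin, at 1.04 ± 0.16 (adjusted p = 0.074 over all genes). HBD went from 92.3, 21.1 and 65.9 CPM with DMSO to 132, 48.0 and 176 CPM with enasidenib, and without the block its log2 fold change was 0.99 ± 0.63. HBB was at 0.27 ± 0.13, HBA1 at 0.72 ± 0.30 and HBA2 at 0.41 ± 0.15, and HBG1, a fetal gamma-globin gene, at 0.06 ± 0.15. Without the block HBA1 was at 0.30, HBA2 at 0.12 and HBG1 at -0.01. Without pair 2 the blocked value was 0.09 for HBB and -0.20 for HBG1 and the list's blocked adjusted p was 0.141, and without pair 3 HBA1 was at 0.17 and HBA2 at 0.22. Without pair 1 HBA1 was at 1.16 and HBA2 at 0.63, and HBD passed over all genes at 1.29 (adjusted p = 1.1e-04).

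Iron handling genes were higher (adjusted p = 0.0046, against 0.056 without the block) and genes of MYC and ribosome biogenesis were lower (adjusted p = 0.012, against 0.056). Without the block both also passed in DESeq2 (0.021 each), with the upper quartile (0.048 each), under the stricter filter (0.024 and 0.025) and on thinned counts (0.035 and 0.045), and iron handling in limma-voom (0.033). With libraries left out and no block, iron handling passed without DMSO replicate 1 (0.0032), enasidenib replicate 2 (7.3e-04), replicate 1 (0.020) or replicate 2 (0.0077) in both groups, and the MYC list without DMSO replicate 2 (1.1e-04), enasidenib replicate 1 (3.2e-06) or replicate 1 in both groups (0.020). In neither list did a member pass, over all genes or adjusted over the list alone. Among 22 iron genes, 7 were higher and 1 lower in all pairs, with SLC11A2, an iron importer, at 0.28 ± 0.14, GLRX5, a factor of iron-sulfur cluster assembly, at 0.27 ± 0.14 and TFRC, the gene of the sorted marker, at 0.18 ± 0.09. Among 28 ribosome biogenesis genes, 10 were lower in all pairs and 0 higher, with BOP1 at -0.46 ± 0.14 and RRP9 at -0.31 ± 0.18. Without pair 3 the blocked adjusted p was 0.797 for iron handling and 0.336 for MYC and ribosome biogenesis, and TFRC was at 0.095, GLRX5 at 0.17 and RRP9 at -0.13. Without pair 1 GLRX5 was at 0.45.

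**Figure D2:**
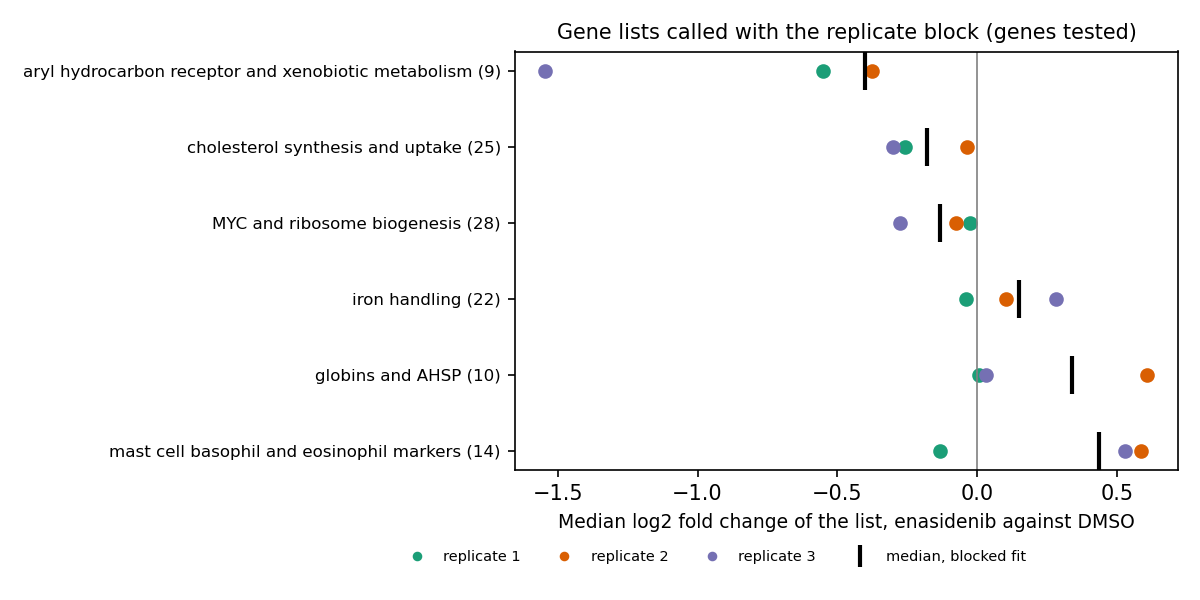
Median log2 fold change (horizontal) over the tested genes of the 6 lists that camera called with the block, for each same-numbered pair (points) and in the blocked model (black bars). The aryl hydrocarbon receptor list lies between -1.54 and -0.38 in the 3 pairs (its median without the block, not drawn, is -0.05), and the mast cell, basophil and eosinophil list is at -0.13 in replicate 1 and at 0.59 and 0.53 in replicates 2 and 3.

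IDH2 and IDH1, the isocitrate dehydrogenase genes in which leukemia mutations occur, had log2 fold changes of -0.08 ± 0.11 (95% interval -0.31 to 0.16) and 0.16 ± 0.11 (-0.09 to 0.40). Without the block they were -0.07 ± 0.23 and 0.17 ± 0.25. In the list of IDH and tricarboxylic acid cycle genes 0 of 22 passed, and SDHD, a subunit gene of succinate dehydrogenase, was at 0.34 ± 0.12. Enzymes of the Jumonji and TET families use 2-oxoglutarate, the product of IDH enzymes, and 0 of 22 genes for such dioxygenases passed, with KDM5C at -0.29 ± 0.11. Neither list was called in any of the list tests with or without the block (camera adjusted p = 0.992 and 0.810 with it).

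Red cell genes outside the globin and iron lists, in the 6 lists below, were not called as groups by camera in edgeR over all 6 libraries, with or without the block. Without the block, single libraries left out gave calls: heme synthesis (adjusted p = 0.044) and the red cell membrane list (6.9e-04) without DMSO replicate 1, and the red cell membrane (7.0e-04), late maturation (0.023) and erythropoietin response (0.043) lists without enasidenib replicate 2. That last step leaves a replicate 2 library, rich in granulocyte transcripts, in the DMSO group only, so those calls are open to this imbalance. In heme synthesis 0 of 14 genes passed (camera adjusted p = 0.331 with the block), and PPOX, protoporphyrinogen oxidase, was at -0.53 ± 0.23 while FECH, ferrochelatase, was at 0.22 ± 0.12. In the list of heme and porphyrin export and breakdown 0 of 9 passed (adjusted p = 0.654), with ABCB6 at -0.49 ± 0.21. ABCG2, an exporter of porphyrins, was at 0.23 ± 0.90, an interval of -1.73 to 2.19 that holds a 2-fold difference in either direction, at levels of 0.210 to 3.17 CPM, and at -0.28 without the block. In the red cell membrane list 0 of 25 passed (adjusted p = 0.702), with DMTN at -0.47 ± 0.12 and ADD2 at 0.57 ± 0.19. Late erythroid maturation had 0 of 27 (adjusted p = 0.126), with MAP1LC3B at 0.35 ± 0.12, and erythroid transcription factors 0 of 18 (adjusted p = 0.460), with E2F2 at -0.32 ± 0.14. The erythropoietin response list had 0 of 19 (adjusted p = 0.238), with CISH at 0.29 ± 0.13. Values that moved by over 1.5 times in the blocked model were those of PPOX (-0.31), FECH (0.14) and ADD2 (0.29) without pair 3 and of ABCB6 (-0.23) without pair 2, and ABCG2 was at -0.65 without pair 1, 0.80 without pair 2 and 0.75 without pair 3.

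Apart from the mast cell, basophil and eosinophil list, the lists of other blood lineages that the CD71 gate could hold were not called by camera in edgeR over all 6 libraries, with or without the block. Without the block, leaving out DMSO replicate 2 gave calls of myeloid (higher, adjusted p = 6.4e-05) and megakaryocyte markers (0.0046), and leaving out enasidenib replicate 2 of myeloid (lower, 3.1e-06) and lymphoid markers (0.041). Either step leaves the granulocyte transcripts of replicate 2 in 1 treatment only. Both myeloid calls follow from that imbalance, and the megakaryocyte and lymphoid calls are open to it. For stem and early progenitor genes 0 of 18 passed (camera adjusted p = 0.992 with the block), with CD34 at 0.31 ± 0.14 and MECOM at 0.39 ± 0.19. For myeloid markers 0 of 15 passed (adjusted p = 0.992, against 0.0041 and higher in limma-voom with the block), with CEBPA at -0.94 ± 0.28 (-0.30 without the block) and CSF1R at 0.47 ± 0.17. Megakaryocyte and platelet markers had 0 of 14 (adjusted p = 0.338) and lymphoid markers 0 of 8 (adjusted p = 0.678), with list medians of 0.22 and -0.28. In the interferon response list 0 of 20 passed over all genes and 1 fell when adjusted over the list alone: RSAD2, the antiviral protein viperin, at -1.07 ± 0.18 (adjusted p = 0.082 over all genes, 0.0025 without pair 1 and 0.0091 without pair 2). Among cell cycle lists, S phase genes had 0 of 28 with MCM7 at -0.29 ± 0.12, and G2 and M phase genes 0 of 28 with CDK1 at 0.32 ± 0.11. S phase genes were called lower without pair 1 in the blocked model (adjusted p = 0.036) and, without the block, without DMSO replicate 2 (0.035) or enasidenib replicate 1 (0.0061), and G2 and M phase genes higher without enasidenib replicate 2 (0.028). Of 24 p53 targets 0 passed, with SESN1 at 0.65 ± 0.18, and of 21 apoptosis regulators 0 passed, with BAK1 at -0.38 ± 0.14. Without pair 3 the blocked values were 0.20 for CD34, -0.43 for CEBPA and -0.15 for MCM7, without pair 1 they were 0.47 for CD34 and -0.45 for MCM7, and without pair 2 -1.44 for CEBPA and 0.42 for SESN1. Among the uncalled lists described here, median and mean log2 fold changes with the block had opposite signs in the 2-oxoglutarate dioxygenase, erythropoietin response, stem cell, myeloid, interferon and G2 and M phase lists, and for p53 targets the list test pointed up while both were below 0. Over all 6 libraries none of the remaining lists was called by camera in edgeR, with or without the block. With pairs left out, the blocked model called immediate early genes (adjusted p = 0.0072) and fetal globin regulators (0.0083) without pair 1 and cytosolic ribosomal proteins without pair 2 (8.7e-04). With libraries left out and no block, lists of oxidative phosphorylation, fatty acid synthesis, lysosome, chaperone, ribosomal protein and immediate early genes were called in at least 1 setting each. Over all 6 libraries fry called 0 of 37 lists, with a lowest adjusted p of 0.989 without the block and 0.438 with it for one direction, and of 0.182 and 0.192 for change in either direction.

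The replicate 2 libraries of both treatments stood apart from the other 4 in their lineage genes. MPO, the granulocyte myeloperoxidase gene, had 16750 CPM in DMSO replicate 2 and 16134 CPM in enasidenib replicate 2, and 34.9 to 54.8 CPM in the other 4 libraries. Myeloid markers together took 2.01% and 2.13% of counts in these libraries, and 0.0199% to 0.0226% in the others. TFRC had 985 and 1136 CPM in replicate 2 against 2303 to 4859 CPM elsewhere, and GATA1, the erythroid master transcription factor, 35.0 and 46.5 CPM against 135 to 150 CPM. Both treatments share this difference, so it enters the comparison without the block as spread within groups.

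**Figure D3:**
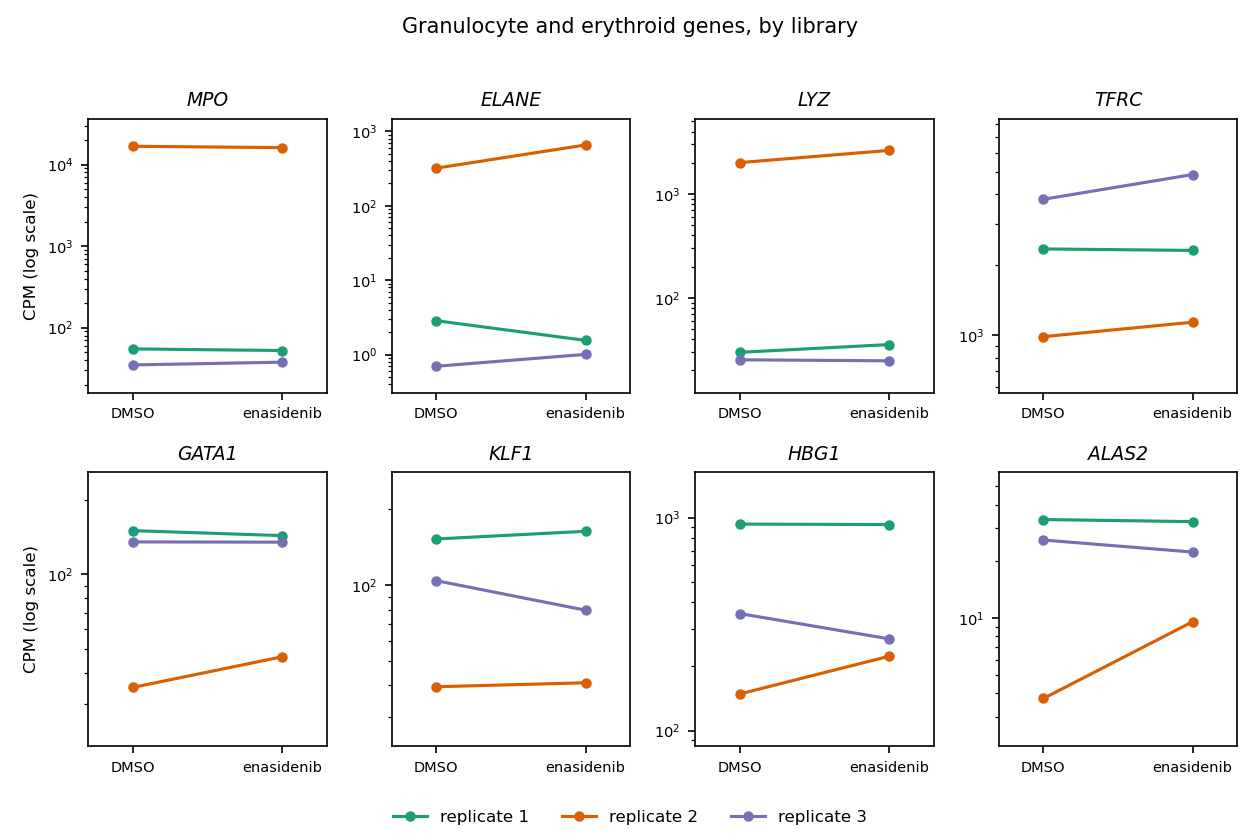
CPM (vertical, log axis) of 8 granulocyte and erythroid genes in the DMSO and enasidenib libraries, with a line joining libraries of the same replicate number. The replicate 2 libraries have the highest MPO, ELANE and LYZ levels and the lowest TFRC, GATA1, KLF1, HBG1 and ALAS2 levels in both treatments.

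The make-up of the libraries differed between treatments by less than the spread between replicates in each of the 4 measures compared. The permutation tests did not use the pairing, so they cannot decide on a shift within pairs. Globin genes took 0.108% ± 0.0910 of counts with DMSO and 0.120% ± 0.0828 with enasidenib (SD, n = 3 each, exact permutation p = 0.7), and the share was higher with enasidenib in 3 of 3 pairs. Cytosolic ribosomal protein genes took 3.01% ± 0.458 and 2.96% ± 0.754 (exact permutation p = 0.9), and the 10 most abundant genes 4.32% ± 0.917 and 4.53% ± 0.978 (exact permutation p = 0.9). The number of genes detected was 15734 ± 739 and 15687 ± 1060 (exact permutation p = 1). The adjusted p over the 4 measures was 1 for each, and the smallest p this design allows is 0.1.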

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

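Blocked models in limma-voom, on thinned counts, without single pairs and with an estimated correlation, and the receptor list without CYP1B1, were chosen after the result was seen, and the other settings were fixed beforehand. The count of changed genes was 0 in edgeR without the block under DESeq2 size factors, the upper quartile, removal of globin genes, no filter, the stricter filter, thinning, an adjusted p under 0.01, a change of at least 2-fold and each of the 9 leave-outs, and 0 in limma-voom. It was 1 (lower) in DESeq2, 7 with the replicate block (0 higher, 7 lower), 27 in DESeq2 with the block (3 higher, 24 lower) and 41 in limma-voom with the block (10 higher, 31 lower). On thinned counts the blocked model called 7 genes, the same 7. Without pair 1 it called 42 (15 higher, 27 lower), without pair 2 it called 9 (0 higher) and without pair 3 it called 5 (0 higher), and 7, 6 and 5 of these were among the 7. The cause was not tested.

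The count of lists called by camera was 2 without the block, 4 in DESeq2, in limma-voom, with the upper quartile and on thinned counts, 5 with the stricter filter, and 6 with the block, in edgeR, in DESeq2 and on thinned counts. It was 8 in limma-voom with the block, and 9, 6 and 4 in the blocked model without pairs 1, 2 and 3. It was 0 with an estimated correlation, with or without the block, and 0 with fry. It ranged from 0 to 12 when libraries or pairs were left out without the block. The test with an estimated correlation has little power at 4 or 2 degrees of freedom. For the mast cell list without the block the estimate was 0.013, near the preset 0.01. Its unadjusted camera p was still 0.099, against 0.030 with the preset. That small estimate was the exception. For the other lists called with the block, estimates without it ran from 0.18 (iron handling) to 0.74 (globins). With the block, estimates for the 6 called lists ran from 0.088 to 0.46, and the mast cell list had 0.36. All of these lie above the preset, so camera p-values with the preset can be too small. Of the lists not called, 3 turned and passed in another setting: myeloid markers were higher without DMSO replicate 2 (adjusted p = 6.4e-05) and in limma-voom with the block (0.0041), chaperones of the endoplasmic reticulum were lower without enasidenib replicate 2 (0.0028), and ribosomal proteins were higher without enasidenib replicate 3 (6.0e-05). Leaving out 1 replicate 2 library leaves the granulocyte transcripts of the other in 1 treatment only. The myeloid call without DMSO replicate 2 follows from that imbalance, and any other call without 1 of these libraries is open to it. The cause of the other turns was not tested. Over the leave-outs, adjusted p ran from 3.1e-06 to 0.958 for myeloid markers, 0.0028 to 0.885 for the chaperones and 1.3e-06 to 0.958 for ribosomal proteins.

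Over 64 genes and 37 lists, the replicate block in edgeR changed no call other than the 7 genes and 4 lists given with it. In DESeq2 and in limma-voom it also added calls of TIPARP (adjusted p = 1.1e-05 and 2.1e-05), HBD (3.4e-06 and 1.7e-05), RSAD2 (3.4e-05 in both), HMGCS1 (0.013 and 0.0063) and CPA3 (0.025 and 0.012), and in limma-voom RNASE2 (0.011), ELANE (8.9e-04) and the lists of myeloid markers and of fetal globin regulators. Among gene results under other settings 1461 kept their side of the threshold and 67 passed it, among list results 912, 74 passed it, 10 lost it and 4 turned. Changes of sign where neither value passed are counted as kept. Planned settings for mitochondrially encoded genes were not run. Thinning to the smallest library left 13701 genes to test in place of 14463, and CYP1B1 at -3.95 with the block.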

Other observations

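The tests of depth and lineage loss for the fall of CYP1B1 and both tests on replicate 2 were chosen only after the result was seen, while the test on other receptor-responsive genes and the counts over splits were fixed before their values were seen.

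The replicate 2 libraries were rich in transcripts of granulocyte precursors beyond MPO. In log2 units, the median of the 15 myeloid markers lay 5.82 above the mean of replicates 1 and 3 with DMSO and 6.47 above it with enasidenib. ELANE, the neutrophil elastase gene, had 321 and 657 CPM there, against 0.699 to 2.86 CPM in the other 4 libraries, and LYZ, the lysozyme gene, 2008 and 2631 CPM against 24.7 to 35.4 CPM. On the same scale the red cell membrane list had medians of -1.07 and -1.44 and the globin list of -1.35 and -0.85. None of the 15 myeloid markers (0) is in another list, and 11 of them had at least 1 CPM in all libraries outside replicate 2. MPO was the most abundant gene in both replicate 2 libraries and ACTB in the other 4.

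A lower erythroid share alone would raise the markers of all other lineages alike. The myeloid median exceeded the highest median among mast cell, megakaryocyte and stem cell lists by 4.80, for the megakaryocyte list (exact Mann-Whitney p = 0.014, with genes that are not independent). That is less than the interquartile range of the myeloid list, 4.97, while the mast cell and stem cell medians lay 5.46 and 5.57 below the myeloid one. An excess over each list larger than this range was looked for, and the megakaryocyte list fell short of it. The medians of the 3 other lists rose by 0.62 to 1.39, against 6.19 for the myeloid list. As shares of counts, myeloid markers took 2.01% and 2.13% in replicate 2 and 0.0199% to 0.0226% elsewhere. Stem cell genes took less there (0.156% and 0.164% against 0.190% to 0.245%), as did megakaryocyte genes, and mast cell genes were mixed. These values argue against a lower erythroid share as the only difference. Granulocyte progenitors among the sorted CD71+ cells are a candidate source, since dividing myeloid progenitors also carry CD71. That stays open. A fall of more than 0.5 in each of 3 erythroid lists was looked for, and the red cell membrane and globin lists gave it in both treatments. The erythroid transcription factor list, which holds genes that myeloid cells also express, did not, with medians of -0.092 with DMSO and -0.33 with enasidenib. Outside that test, heme synthesis (-0.27 and -0.31) and late erythroid maturation (-0.25 and -0.18) fell by less than 0.5 too. Erythroid lists were thus not lower to a like degree. The titles of replicates 2 and 3 carry the letters cb before the number, which may stand for separate cord blood units. The labels do not explain the letters, and a difference between units stays open, untested.

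CYP1B1, AHRR and TIPARP were lower with enasidenib in 3 of 3 pairs each. CYP1B1 stayed at -3.95 (blocked log2 fold change) with every library thinned to one total. Thinning keeps the expected ratio of a gene with this many counts, so that test could not decide on depth. In replicate 1 the enasidenib library was the deeper one (54610969 counts against 37141122), and all 3 genes were lower in it too. Loss of all the cells that a lineage list covers is argued against, since it would lower the list's markers together by at least the fall it explains. The lowest blocked median among 5 lineage lists was -0.28, for lymphoid markers, with an interquartile range of 0.36. It lay 0.81 above the smallest fall of the 3 genes, -1.09 ± 0.18 for TIPARP, and the medians of the other 4 lists lay 1.12 to 1.53 above it, with interquartile ranges of 0.41 to 0.67. Only 4 of the 8 tested lymphoid markers had a mean log2 CPM of at least 2, with a median of -0.23. Loss of a lineage outside these lists, of 1 cell type among several pooled in a list, or of a few cells whose markers red cell precursors also carry, stays open. Lower activity of the aryl hydrocarbon receptor in treated cells is a candidate explanation and stays open. Of 6 other genes known to respond to the receptor, 5 could be tested, their median was 0.042 with an interquartile range of 0.44, and 0 were lower in all pairs, a spread too wide to decide.

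The count of genes changed was set against other splits of the same libraries. Without the block the real split gave 0 genes and the highest of the other 9 splits gave 0, with 10 of 10 splits at 0 or more. No split can give fewer than 0 genes, so that share was fixed and decides nothing. With the block, 4 splits part all 3 pairs, the real one gave 7 genes and the highest of the others 0, with 1 of 4 splits at 7 or more. Both designs have too few splits for a share under 0.05.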
